A study of Mus musculus with 32 samples.

How the data were processed

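Messenger RNA of mouse mesentery was measured on 32 Affymetrix Mouse Genome 430 2.0 arrays, 1 sample per array. Per the labels' protocols, tissue RNA was taken with TRIzol, cleaned on RNeasy columns, and amplified and labelled with MessageAmp II from 1 µg. Each value is the intensity of a probe set on a linear scale, as deposited by the authors. The submitters' processing notes name GCOS and MAS5, with versions not given in the sources used here; MAS5 reduces the probes of a set to 1 signal and scales each array. The deposited intensity values have a 2% trimmed mean of 500 on every array, and 13 values are 0. The series text names ANOVA in Partek Genomics Suite as the authors' test, with settings not given in the sources used here. Per-probe values were not used here, so background and probe effects could not be changed. For arrays, their number limits the precision: 3 or 4 per group within a code series.

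Groups came from the strain and treatment labels, and replicate numbers follow accession order and only name an array. Title codes fall into 3 series. The labels do not say what the codes mean, and they are treated here as sets of arrays that may have been handled together. Every pristane response had controls of the same strain in its own code series.

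Of 45101 probe sets, 34958 carried 1 gene symbol, 932 several and 9211 none in the platform annotation used here; 64 are array controls. Symbols were checked against RefSeq names of the mouse assembly GRCm38.p6, and 0 were updated. Probe sets with several symbols or none named no gene. A probe set was kept if its signal was above 103.7, the median over all values, on at least 3 arrays, which left 27039. Each of the 13016 genes tested, of 18193 on the array, was represented by its brightest probe set; 6038 genes have more than 1. Signals were tested as log2(signal + 24.9), where 24.9 is the 25th percentile of all values, so changes of dim genes are understated.

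All arrays entered 1 linear model with a term for each group and each code series, fitted with limma 3.58.1 in R 4.3.3 with an intensity trend in the moderated variance. Contrasts gave the 5 responses to treatment, the differences between them, the DBA and F1 control comparisons and the control difference between code series. Tests are two-sided, with Benjamini-Hochberg adjustment over the genes of a contrast, and "called", "rose" and "fell" stand for an adjusted p under 0.05. Because the model has a level for each group in each series, a response uses only arrays of its own series for its size, and all 32 for its spread.

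The design, the alternatives and 30 gene lists of pathways and cell types were fixed before the data were examined. The lists hold 484 symbols, of which 430 matched and 54 did not. Camera tested 28 lists per contrast against the other genes with a preset correlation of 0.01; the remaining lists had fewer than 3 tested genes and got no test. A correlation estimated from the arrays and fry were alternatives. A list's members are not independent of the members of related lists.

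The rule for named genes took, per response, the 8 largest increases and 6 largest decreases with an adjusted p under 0.05 and every treated array beyond every same-strain control of its series. For other contrasts it took 6 and 6 with an adjusted p under 0.05. From each list it took up to 4 members with the largest change. The Ifi200 family, Cdkn2a and Mtor were named throughout, and predicted or clone-named genes were skipped. Members of lists with 5 or fewer called, clock genes, sex-linked markers and other genes outside the rule were named after their values were seen. Not every gene the rule takes is printed.

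Alternatives changed 1 choice at a time: a floor or nothing in place of the offset, no dim filter or a stricter one (519.2), quantile normalization, median centring, no code series term, a separate fit per comparison, no variance trend, an ordinary linear model, array weights, the mean over a gene's probe sets, probe sets singly, and each array left out. Alternatives chosen after seeing the data were a term for Xist, parental controls for F1, and leaving out BALB/c control replicate 2. Other splits of the arrays, at most 100 per comparison, were counted.

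The procedure was tested on simulated data with 100 genes of 13016 changed by 1 and 100 by 2 log2 units. It recovered 75% and 96% in the BALB/c day 3 response, 66% and 94% in DBA day 3, 86% and 98% in BALB/c day 18, 48% and 87% in BALB/c against DBA at day 3, and 80% and 96% in DBA against BALB/c controls. Of all calls, 4.47%, 6.43%, 3.16%, 7.53% and 5.38% were false.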

Results

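Messenger RNA was measured in mouse mesentery, the fold of peritoneum that carries fat, vessels and lymphoid tissue to the gut, on 32 oligonucleotide arrays. Pristane (TMPD) is a mineral oil hydrocarbon that sets up a long-lasting granulomatous inflammation in the peritoneal cavity, and in BALB/c mice it leads to plasmacytomas, tumours of plasma cells, whereas DBA mice are largely resistant. Treated animals received 0.5 ml intraperitoneally, and the tissue was taken on day 3 or day 18. The groups were BALB/c at day 3 (3 arrays) and day 18 (4), DBA at day 3 (3) and day 18 (3), the F1 of both strains at day 3 (3), and untreated BALB/c (7), DBA (6) and F1 (3) controls. Of 3 series of title codes, the day 3 code series holds all day 3 arrays with 3 control arrays of each strain. The BALB/c day 18 code series holds 4 treated and 4 control arrays, and that of DBA day 18 holds 3 and 3. Each response to treatment compares treated arrays with same-strain controls of their own code series, and no array is shared by a pair of responses. List results are given as the numbers of members that rose and fell over all genes tested, with the median log2 change. Where no other count follows, the count adjusted over the list alone was the same, and where no adjusted p with an estimated correlation follows, the list's call held with it. Where a group averaged under the dim filter of 103.7, the size and rank of a change, and a list median resting on it, depend on the offset added before the log. This holds for the controls of 6 of the 8 largest increases in each day 3 response, 5 in BALB/c and 7 in DBA at day 18. The labels do not say that the arrays of a group came from separate animals, so p-values measure only the spread between arrays, which may be technical.

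Array median signals ran from 90.6 to 135.3. Replicate arrays correlated at 0.97 to 0.988, except BALB/c control replicate 2, whose highest correlation with any array was 0.891. On that array the 20 brightest probe sets held 5.31% of the signal. The pancreatic acinar markers had a mean log2 signal of 16.7 there, 9.784 and 10.09 on BALB/c control replicates 3 and 4 and 11.97, 10.87 and 13.4 on BALB/c day 18 replicates 2 to 4, so they were high on 6 of the 8 arrays of the BALB/c day 18 code series. On the other 2 they stood at 6.712 and 6.52, against a median of 6.206 over all arrays. Xist, the transcript that silences an X chromosome in female cells, was high on 21 arrays and low on 11, and Kdm5d, which lies on the Y chromosome, showed the opposite pattern on each. The labels give no sex. All 3 treated F1 arrays were high in Xist and all 3 F1 control arrays were low, whereas the other treated groups had the same numbers of high and low arrays as their controls. The 3' to 5' signal ratio of beta-actin, which rises as RNA shortens from its 5' end, was higher in the day 3 code series controls, at 2.42 ± 0.275 in BALB/c, 2.1 ± 0.0416 in F1 and 2.44 ± 0.382 in DBA (SD, n = 3), than in the treated arrays, at 1.88 ± 0.298, 1.56 ± 0.17 and 1.93 ± 0.085. In the day 18 series it was 1.56 ± 0.49 in BALB/c controls and 1.18 ± 0.045 in treated arrays (SD, n = 4), and 1.29 ± 0.0493 and 1.19 ± 0.0361 in DBA (SD, n = 3).

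The first comparison asked what pristane did to the BALB/c mesentery by day 3. The largest increases were led by Arg1, the arginase of activated macrophages, which rose by 7.78 ± 0.64 on the log2 scale (SE; 3 treated and 3 control arrays), the neutrophil chemokine gene Cxcl5 by 6.69 ± 0.47, and the calprotectin genes S100a9 and S100a8 by 6.08 ± 0.50 and 6.04 ± 0.48. The chitinase-like Chil3 rose by 6.56 ± 0.42, the acute-phase gene Saa1 by 5.57 ± 0.36, Acod1, which makes itaconate in activated macrophages, by 5.36 ± 0.35, and Oas3, an interferon-induced oligoadenylate synthetase, by 5.17 ± 0.39. The largest decreases were in Inmt (-3.14), Tmem45b (-2.91), Timp4 (-2.88), Ccn5 (-2.60), Paqr9 (-2.41) and Depp1 (-2.41). Of 13016 genes tested, 4618 changed, 2380 higher and 2238 lower, and 1087 and 493 of these by at least 2-fold.

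Interferon-induced genes rose together in BALB/c at day 3. Among the type I interferon-stimulated genes 29 of 30 rose and 1 (Ifi27l2a) fell (median 2.12, adjusted p = 7.8e-21, adjusted p = 0.088 with an estimated correlation). In the list of interferon-gamma response genes and GTPases 11 of 14 rose (median 1.48, adjusted p = 5.8e-06, adjusted p = 0.16 with an estimated correlation), with Irf8 (1.91), Irgm2 (1.81) and Cxcl10 (1.76) as examples. For MHC class I antigen presentation 6 of 11 rose, 7 adjusted over the list alone (median 0.51, adjusted p = 0.032, adjusted p = 0.38 with an estimated correlation), led by the peptide transporter gene Tap1 (1.70) and the immunoproteasome gene Psmb8 (1.36). This list's call ended without BALB/c day 3 replicate 3 (0.37, adjusted p = 0.17) or BALB/c control replicate 5 (0.45, adjusted p = 0.1); its adjusted p ran from 0.0037 to 0.17 over its alternatives with the preset correlation, as do the ranges given for other lists. The MHC class II list was not called, with 2 of 8 higher (H2-Oa and Ctss, the latter by 2.46), and a median of 0.12 (adjusted p = 0.52).

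Leukocyte and inflammation lists also rose. Of the acute inflammatory cytokines and chemokines, 21 of 25 rose (median 2.59, adjusted p = 2.3e-15); Cxcl2 and Ccl2, which attract neutrophils and monocytes, rose by 5.02 and 4.90. In the acute-phase and complement list 11 of 14 rose and 1 (Orm1) fell (median 1.40, adjusted p = 4.8e-08). Of the neutrophil markers 13 of 18 rose, 14 adjusted over the list alone (median 2.93, adjusted p = 5.8e-10, adjusted p = 0.092 with an estimated correlation). Among monocyte and macrophage markers 19 of 22 rose (median 2.17, adjusted p = 2.3e-15, adjusted p = 0.088 with an estimated correlation), including Fcgr1 (3.59), Trem2 (3.43) and Clec7a (3.42). For alternatively activated macrophage markers 10 of 13 rose (median 1.61, adjusted p = 3.3e-08), with Clec10a (2.12) and Mrc1 (1.97) next to Arg1 and Chil3. Of the plasma cell markers 8 of 13 rose (median 1.28, adjusted p = 0.0021, adjusted p = 0.092 with an estimated correlation), among them Mzb1 (2.35), Ighm (1.87) and Jchain (1.76). In the T and NK cell list 9 of 18 rose, 10 adjusted over the list alone (median 0.76, adjusted p = 0.011, adjusted p = 0.34 with an estimated correlation). Mast cell markers were not called as a list, at 0.16 (adjusted p = 0.41), although Hdc, the histamine-forming decarboxylase, rose by 4.03.

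Fat genes fell while matrix and cell-cycle genes rose. In the adipocyte identity list 12 of 17 fell, 14 adjusted over the list alone (median -1.21, adjusted p = 2.3e-05, adjusted p = 0.3 with an estimated correlation), with Aqp7, the glycerol channel of adipocytes (-1.88), Slc2a4 (-1.81) and Pparg (-1.54) among the decreases. For lipid synthesis 13 of 18 fell, 17 adjusted over the list alone (median -1.14, adjusted p = 2.5e-05, adjusted p = 0.34 with an estimated correlation), led by Pck1 (-2.39) and Acacb (-1.75). Of the matrix and fibrosis genes 10 of 22 rose (median 0.33, adjusted p = 0.0049, adjusted p = 0.37 with an estimated correlation), with Timp1 (4.44) and Lox (2.23) the largest. Of the matrix proteases 8 of 12 rose, 10 adjusted over the list alone (median 0.93, adjusted p = 8.8e-05, adjusted p = 0.088 with an estimated correlation). Proliferation genes rose almost throughout: 26 of 27 rose, 26 with 1 lower adjusted over the list alone (median 2.59, adjusted p = 3.9e-19, adjusted p = 0.088 with an estimated correlation).

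Lists of other cell types and of stress were not called in BALB/c at day 3. Of the endothelial markers 4 of 15 (Selp, Vcam1, Icam1 and Madcam1) rose and 6 fell, 4 and 9 adjusted over the list alone (median -0.48, adjusted p = 0.29), with the adhesion genes Vcam1 (2.12) and Icam1 (1.83) higher and the vessel receptor gene Kdr (-1.23) lower. Of the hypoxia and stress genes, 4 of 16 (Hif1a, Slc2a1, Hmox1 and Mt2) rose and 1 (Vegfa) fell, 5 and 1 adjusted over the list alone (median 0.14, adjusted p = 0.29). Medians were 0.14 for smooth muscle (adjusted p = 0.97), 1.14 for pancreatic acinar (adjusted p = 0.58), -0.56 for intestinal epithelial (adjusted p = 0.58), -0.02 for skeletal muscle (adjusted p = 0.72) and 0.09 for neuronal and glial markers (adjusted p = 0.97). In each, 0 members were called by limma at an adjusted p of 0.05. B cell markers, of which 2 of 12 (Blk and Cxcr5) fell, 0 adjusted over the list alone, had a positive median (0.11) and mean (0.08) but a negative test direction (adjusted p = 0.99). So had the mesothelial markers (0.05 and 0.03, adjusted p = 0.96), of which 1 of 13 (Wt1) rose and 2 (Upk3b and Gpm6a) fell. In the list of plasmacytoma locus candidates 3 of 6 (Mndal, Tnfrsf1b and Myc) rose and 1 (Rb1) fell (median 0.34, adjusted p = 0.65), with Tnfrsf1b at 1.33 and Myc at 0.89. Limma gave these tests with Benjamini-Hochberg adjustment, and 5667 genes had an unadjusted p under 0.05.

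**Figure D1:**
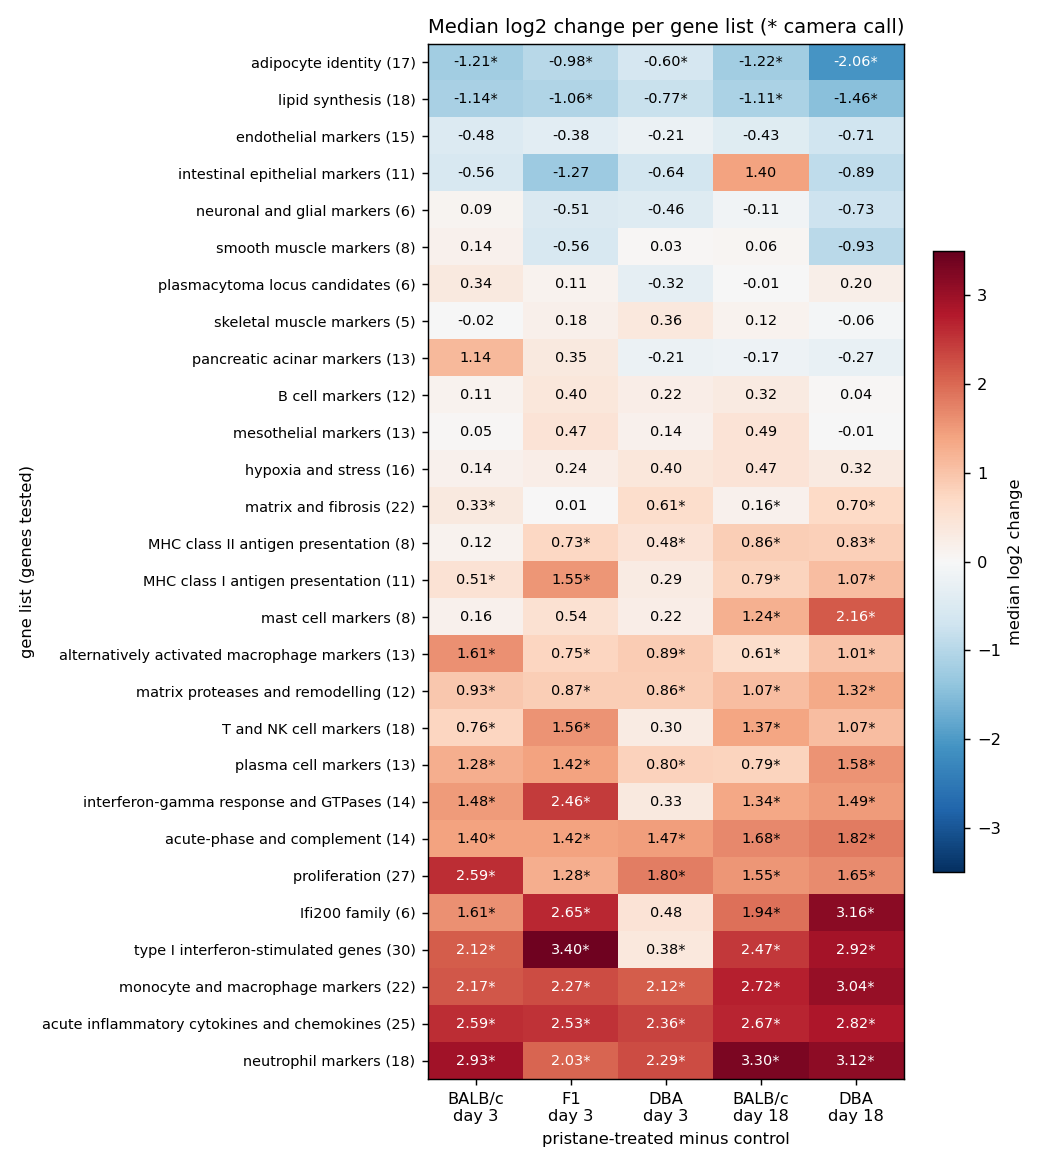
Heat map of the median log2 change (colour, log2 units) of each fixed gene list, with the number of genes tested in brackets, in the 5 responses to pristane; an asterisk marks lists called by camera with the preset correlation. The type I interferon-stimulated genes stand at 2.12 in BALB/c, 3.40 in F1 and 0.38 in DBA at day 3, and at 2.47 and 2.92 in BALB/c and DBA at day 18.

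The F1 mice were compared with F1 controls at day 3. Besides Xist (signal 15000 in treated and 89.3 in control arrays) and the Y-linked Eif2s3y (7.07 and 1560) and Kdm5d (3.57 and 567), which separate the treated from the control arrays, the largest increases were in Acod1 (6.13), Arg1 (5.83), Ms4a4c (5.70), Cxcl5 (5.57), Oas3 (5.46), Il1rn (5.11) and Slfn1 (5.04). Ms4a4c and Slfn1 are induced by interferon. Of the decreases outside the Y chromosome the largest were in Timp4 (-3.43) and Inmt (-3.28). In total 4752 genes changed, 2415 higher and 2337 lower, with 1060 and 505 at 2-fold or more, among 3 treated and 3 control arrays. At an unadjusted p under 0.05 there were 5828.

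The interferon lists rose in F1 mice too. For type I interferon-stimulated genes 29 of 30 rose (median 3.40, adjusted p = 2.5e-33), and Irf7 (4.49), Dhx58 (4.40) and Zbp1 (4.36) were examples. Among interferon-gamma response genes and GTPases 13 of 14 rose (median 2.46, adjusted p = 5.2e-13), with Cxcl10 at 4.74 ± 0.39 and Iigp1 and Igtp at 2.81 and 2.74. MHC class I antigen presentation moved likewise: 8 of 11 rose (median 1.55, adjusted p = 6.4e-06, adjusted p = 0.07 with an estimated correlation). Of the MHC class II genes 4 of 8 (H2-Ab1, H2-DMa, H2-Oa and Ctss) rose (median 0.73, adjusted p = 0.0022, adjusted p = 0.25 with an estimated correlation).

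Most leukocyte lists rose in F1. Of the cytokines and chemokines 19 of 25 rose, 20 adjusted over the list alone (median 2.53, adjusted p = 1.8e-13). In the acute-phase and complement list 11 of 14 rose and 1 (Orm1) fell (median 1.42, adjusted p = 1.2e-07). Among neutrophil markers 11 of 18 rose, 15 adjusted over the list alone (median 2.03, adjusted p = 1.2e-07, adjusted p = 0.15 with an estimated correlation), led by S100a9 (4.87) and S100a8 (4.64). Among monocyte and macrophage markers 20 of 22 rose (median 2.27, adjusted p = 3.1e-17). Of the alternatively activated macrophage markers 7 of 13 rose (median 0.75, adjusted p = 0.00066, adjusted p = 0.13 with an estimated correlation). For T and NK cells 13 of 18 rose (median 1.56, adjusted p = 4.2e-07). Of the plasma cell markers 8 of 13 rose, 10 adjusted over the list alone (median 1.42, adjusted p = 0.00013). The B cell (0.40, adjusted p = 0.073; Ms4a1, Fcrla and Ly6d, 3 of 12, rose) and mast cell lists (0.54, adjusted p = 0.13; Tpsab1, Fcer1a and Hdc, 3 of 8, rose) were not called. The B cell list was called without F1 day 3 replicate 1 (0.53, adjusted p = 0.037) or F1 control replicate 3 (0.49, adjusted p = 0.042), over a range of 0.023 to 0.6.

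Fat genes fell in F1: of the adipocyte identity list 11 of 17 fell, 13 adjusted over the list alone (median -0.98, adjusted p = 0.00042, adjusted p = 0.33 with an estimated correlation). Of the lipid synthesis list 13 of 18 fell, 16 adjusted over the list alone (median -1.06, adjusted p = 3.8e-05, adjusted p = 0.33 with an estimated correlation). Of the matrix proteases 6 of 12 rose, 7 adjusted over the list alone (median 0.87, adjusted p = 0.00046, adjusted p = 0.12 with an estimated correlation). The matrix and fibrosis list was not called: 5 of 22 (Col5a1, Timp1, Thbs1, Tgfbi and Pdgfra) rose and 2 (Col12a1 and Acta2) fell, 4 and 2 adjusted over the list alone (median 0.01, adjusted p = 0.53). For proliferation 25 of 27 rose, 25 with 1 lower adjusted over the list alone (median 1.28, adjusted p = 6.6e-08, adjusted p = 0.25 with an estimated correlation). The intestinal epithelial list (-1.27, adjusted p = 0.051, with Vil1 and Lgals4, 2 of 11, lower, 1 adjusted over the list alone) was called without F1 control replicate 2 or 3 (-1.95 and -1.94, adjusted p = 0.0015 and 0.01), over a range of 0.0015 to 0.77. Log2 levels of F1 controls (mean 7.58) ran from 6.13 to 10.32, so 1 array carried most of the fall. The smooth muscle list (-0.56, adjusted p = 0.23, with Mylk, 1 of 8, lower, 0 adjusted over the list alone) was called without F1 day 3 replicate 2 (-1.17, adjusted p = 0.012) or control replicate 3 (-1.06, adjusted p = 0.042), over a range of 0.012 to 0.88. Log2 levels overlapped (9.99 to 12.77 treated, 11.17 to 13.01 control), so no fall was shown.

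In DBA mice the same comparison was made at day 3, with 3 treated and 3 control arrays. The largest increases were in Arg1 (7.88), Cxcl2 (6.05), Mmp12 (5.63), S100a9 (5.50), S100a8 (5.43), Acod1 (5.41), Cxcl5 (5.40) and Clec4e (5.23), and the largest decreases in the fatty acid elongase gene Elovl3 (-2.70), the lipase gene Lipg (-2.51), Acacb (-2.46), Slc2a5 (-2.22), Slc13a4 (-2.21) and Gsta3 (-2.19). Of the interferon-induced genes, Zbp1 rose by 1.85 ± 0.27, Oasl1 by 1.57 and Bst2 by 1.17, while Cxcl10 stood at 0.90 ± 0.39 (adjusted p = 0.083). Oas3 (1.32 ± 0.39, adjusted p = 0.011) was no longer called without DBA day 3 replicate 1 (0.96, adjusted p = 0.11), over a range of 0.00081 to 0.11 among its alternatives. Altogether 3877 genes changed, 2131 higher (55%) and 1746 lower, 818 and 306 of them at least 2-fold; median centring called 4065, of which 41% were higher. At an unadjusted p under 0.05 there were 5126.

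Of the type I interferon-stimulated genes in DBA 12 of 30 rose (median 0.38, adjusted p = 0.0014, adjusted p = 0.6 with an estimated correlation). In the interferon-gamma and GTPase list 4 of 14 (Irgm2, Irf1, Irf8 and Socs1) rose and 1 (Cxcl9) fell (median 0.33, adjusted p = 0.064). The interferon-gamma list was called without DBA day 3 replicate 1 (0.37, adjusted p = 0.043) or DBA control replicate 5 (0.53, adjusted p = 0.011), over a range of 0.011 to 0.17. MHC class I presentation was not called, and 1 of 11 (Tap1) rose, 0 adjusted over the list alone (median 0.29, adjusted p = 0.12). For MHC class II 3 of 8 (H2-Ab1, Cd74 and Ctss) rose (median 0.48, adjusted p = 0.018, adjusted p = 0.5 with an estimated correlation). Ctss was at 2.71.

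Inflammatory lists rose in DBA at day 3. For cytokines and chemokines 20 of 25 rose, 21 adjusted over the list alone (median 2.36, adjusted p = 1.8e-14). For acute-phase and complement genes 12 of 14 rose, 12 with 1 lower adjusted over the list alone (median 1.47, adjusted p = 1.8e-09). In the neutrophil list 9 of 18 rose, 12 adjusted over the list alone (median 2.29, adjusted p = 1.8e-09, adjusted p = 0.17 with an estimated correlation). Among monocyte and macrophage markers 22 of 22 rose (median 2.12, adjusted p = 1.1e-21). Of the alternatively activated set 8 of 13 rose (median 0.89, adjusted p = 2.7e-06, adjusted p = 0.057 with an estimated correlation). In the plasma cell list 5 of 13 (Mzb1, Sdc1, Ighm, Pou2af1 and Sdf2l1) rose and 1 (Irf4) fell, 7 and 1 adjusted over the list alone (median 0.80, adjusted p = 0.022, adjusted p = 0.27 with an estimated correlation). The list's call ended without DBA day 3 replicate 2 (0.59, adjusted p = 0.087) or DBA control replicate 4 (0.82, adjusted p = 0.064), over a range of 0.00064 to 0.13. T and NK cell markers were not called, and 6 of 18 rose (median 0.30, adjusted p = 0.15).

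Of the adipocyte identity genes 2 of 17 (Cidea and Retn) fell, 0 adjusted over the list alone (median -0.60, adjusted p = 0.03, adjusted p = 0.6 with an estimated correlation). This downward call ended without DBA day 3 replicate 1 (-0.58, adjusted p = 0.052) or DBA control replicate 4 (-0.41, adjusted p = 0.1), over a range of 0.00025 to 0.1. For lipid synthesis 9 of 18 fell, 10 adjusted over the list alone (median -0.77, adjusted p = 0.00014, adjusted p = 0.51 with an estimated correlation). Matrix and fibrosis genes rose: 13 of 22 rose, 13 with 1 lower adjusted over the list alone (median 0.61, adjusted p = 7.5e-05, adjusted p = 0.27 with an estimated correlation), with Timp1 (4.33), Lox (1.60) and Col1a1 (1.44). Of the proteases 8 of 12 rose, 9 adjusted over the list alone (median 0.86, adjusted p = 1.7e-05, adjusted p = 0.078 with an estimated correlation), with Mmp14 (1.73) after Mmp12. Of the proliferation genes 26 of 27 rose (median 1.80, adjusted p = 8.4e-13, adjusted p = 0.21 with an estimated correlation).

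Whether the strains responded differently at day 3 was tested as the difference between responses. BALB/c exceeded DBA in interferon-stimulated genes: Oas3 (3.85), Slfn1 (3.30), Usp18 (2.95) and Ifit1 (2.59) differed, where Usp18 encodes the protease that removes ISG15, and Pla2g2e, a secreted phospholipase gene, differed by 4.18 ± 0.40 (adjusted p = 1.1e-06). Of the type I interferon-stimulated genes, 14 of 30 were higher in the BALB/c response, 28 higher and 1 lower adjusted over the list alone, with a median difference of 1.56 (adjusted p = 5.2e-43). DBA exceeded BALB/c in Il1a (-2.19), Rarres1 (-2.19), Best1 (-2.18) and Fcrls (-1.94). Marco, of the monocyte and macrophage list, was called in the same direction. Its call ended without BALB/c day 3 replicate 1 (-4.21, adjusted p = 0.05). Camera called 8 of 28 lists. The interferon-gamma and GTPase list (0.91, adjusted p = 4.9e-07, adjusted p = 0.34 with an estimated correlation; 0 of 14 were called, 6 adjusted over the list alone) was higher in BALB/c. So were the proliferation list (0.90, adjusted p = 3.2e-11; 0 of 27, 10 adjusted over the list alone) and the alternatively activated macrophage list (0.39, adjusted p = 0.013; 0 of 13, 3 adjusted over the list alone). For these 2 adjusted p = 0.45 with an estimated correlation. Lower in BALB/c were the adipocyte list (-0.77, adjusted p = 0.00036, adjusted p = 0.57 with an estimated correlation; 0 of 17, 1 adjusted over the list alone) and the mesothelial list (-0.39, adjusted p = 0.014, adjusted p = 0.57 with an estimated correlation; 0 of 13, 2 adjusted over the list alone). The MHC class II list was lower too (-0.36, adjusted p = 0.033, adjusted p = 0.58 with an estimated correlation; 0 of 8, 1 adjusted over the list alone). The mesothelial call ended without BALB/c control replicate 7, DBA day 3 replicate 3 or DBA control replicate 4 (-0.38 to -0.18, adjusted p = 0.092 to 0.16), over a range of 0.0011 to 0.4. The MHC class II call ended without BALB/c day 3 replicate 1 or 2, BALB/c control replicate 2, 6 or 7, DBA day 3 replicate 2 or DBA control replicate 4 or 6 (-0.36 to -0.25, adjusted p = 0.064 to 0.14), over a range of 0.0034 to 0.14. The monocyte and macrophage list showed no call (-0.01, adjusted p = 0.56), except without DBA day 3 replicate 3 (-0.19, adjusted p = 0.037) over a range of 0.037 to 0.94. Over all genes 65 differed, 49 higher and 16 lower in BALB/c, with 1288 at an unadjusted p under 0.05. That count was 23, 32, 34, 30, 36, 27 or 29 without BALB/c day 3 replicate 1 or 3, BALB/c control replicate 5 or 6, DBA day 3 replicate 2 or 3, or DBA control replicate 5, in that order. It was 200 without BALB/c control replicate 2, which enters only through the shared estimate of spread.

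The F1 response was then set against each parent. Against DBA camera called 7 of 28 lists. Ifi44l (4.94), Ms4a4c (4.31), Irf7 (4.30), Usp18 (4.23), Oas3 (4.14) and Cxcl9 (4.13) were larger in F1, and Rarres1 (-1.84) and Cd209a (-1.79) were smaller. Of the type I list, 28 of 30 were larger in F1, 29 adjusted over the list alone, with a median of 2.67 (adjusted p = 2.1e-74). The interferon-gamma list (10 of 14, 12 adjusted over the list alone; 1.87, adjusted p = 3.1e-23), MHC class I (6 of 11, 8 adjusted over the list alone; 1.27, adjusted p = 4.2e-08) and T and NK cells (7 of 18, 8 adjusted over the list alone; 0.97, adjusted p = 9.8e-10) did the same. Plasma cell markers were also larger (0.60, adjusted p = 0.008, adjusted p = 0.19 with an estimated correlation). A total of 263 genes differed, 219 larger and 44 smaller, with 1676 at an unadjusted p under 0.05, and 534 without BALB/c control replicate 2.

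Against BALB/c, F1 was higher in Cxcl10 (2.98 ± 0.55, adjusted p = 0.013), Col4a6 (2.74) and the guanylate-binding protein gene Gbp8 (2.42), and lower in Pla2g2e (-3.15) and Pmepa1 (-1.71). The Cxcl10 call ended without BALB/c day 3 replicate 1 (2.66, adjusted p = 0.067) or BALB/c day 3 replicate 2 (2.60, adjusted p = 0.069), over a range of 3.8e-05 to 0.07. No type I interferon-stimulated gene passed alone over all genes (0 of 30 with limma), but 24 did adjusted over the list alone, and the list's median was 0.99 (adjusted p = 1.4e-24, adjusted p = 0.055 with an estimated correlation). The interferon-gamma (0.96, adjusted p = 4.3e-13), MHC class I (0.98, adjusted p = 2.6e-08) and T and NK cell lists (0.85, adjusted p = 9e-08) were larger in F1, and the proliferation (-1.20, adjusted p = 2.3e-20) and alternatively activated macrophage lists (-1.16, adjusted p = 1.3e-06) smaller. For these lists adjusted p = 0.051 to 0.073 with an estimated correlation, and camera called 14 of 28 lists in all. The intestinal epithelial list (-0.90, adjusted p = 0.037, adjusted p = 0.67 with an estimated correlation; 0 of 11 called) turned to 0.40 (adjusted p = 0.71) without F1 control replicate 1. Its call ended without BALB/c day 3 replicate 3 or BALB/c control replicate 2 or 5 (-0.90 to -0.85, adjusted p = 0.077 to 0.092), over a range of 7.5e-05 to 0.92. Over all genes 29 differed, 22 higher and 7 lower, with 1143 at an unadjusted p under 0.05. Leaving out 1 array gave 12, 6, 55, 14, 16, 7, 16 and 16 for BALB/c day 3 replicates 1, 2 and 3, BALB/c control replicates 5 and 7, F1 day 3 replicate 3 and F1 control replicates 2 and 3, and 166 for BALB/c control replicate 2. With a term for Xist, chosen after seeing the data, 5 genes differed, and with parental controls in place of the F1 controls, also chosen after seeing the data, 180.

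**Figure D2:**
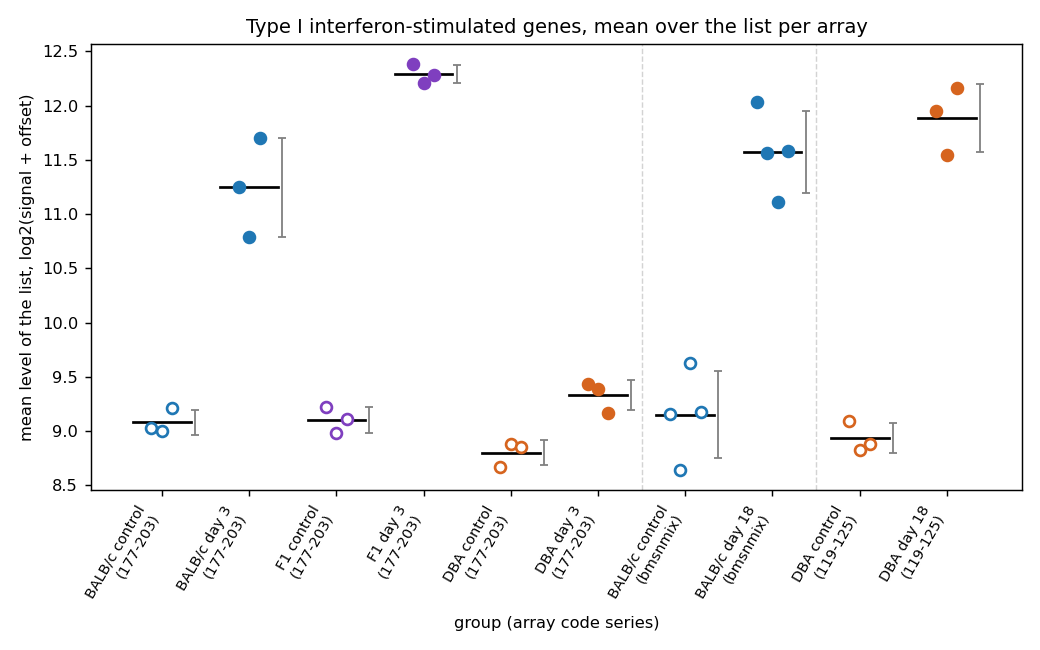
Mean log2(signal + offset) of the 30 type I interferon-stimulated genes on each array (vertical axis, log2 units) by strain and day; open symbols are controls, filled symbols treated arrays, black bars group means and grey bars SD, and dashed lines part the code series. Control groups lie between 8.80 ± 0.11 and 9.15 ± 0.4, DBA day 3 at 9.33 ± 0.14, BALB/c day 3 at 11.25 ± 0.46 and F1 day 3 at 12.29 ± 0.09.

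At day 18 the BALB/c response was measured on 4 treated and 4 control arrays. The largest increases were these: Arg1 rose by 6.92 ± 0.55 (SE), Cxcl5 by 6.65 ± 0.41, Acod1 by 6.64 ± 0.30, the C-type lectin receptor gene Clec4e by 6.08 ± 0.27, Il1rn by 5.74 ± 0.32, Cxcl2 by 5.59 ± 0.32, S100a8 by 5.58 ± 0.42 and S100a9 by 5.54 ± 0.43. The decreases were led by Reep6 (-2.38), Sntb1 (-2.37), Pck1 (-2.23), Agt (-2.19), Paqr9 (-2.18) and Klb (-2.07), where Agt encodes angiotensinogen. In all, 5715 genes changed, 2825 higher and 2890 lower, with 1172 and 546 at 2-fold or more and 6558 at an unadjusted p under 0.05. In these arrays the mean log2 level of pancreatic acinar markers was 10.69 ± 2.97 in the treated and 10.82 ± 4.21 in the control arrays, and that of intestinal epithelial markers 7.69 ± 1.37 and 6.32 ± 0.33 (SD, n = 4).

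Interferon lists rose at day 18 in BALB/c. Among type I interferon-stimulated genes 29 of 30 rose and 1 (Ifi27l2a) fell (median 2.47, adjusted p = 6e-22, adjusted p = 0.079 with an estimated correlation). In the interferon-gamma and GTPase list 12 of 14 rose (median 1.34, adjusted p = 4.9e-07, adjusted p = 0.12 with an estimated correlation). For MHC class I 8 of 11 rose (median 0.79, adjusted p = 0.0026, adjusted p = 0.21 with an estimated correlation), with Psmb8 (1.68) and Tap1 (1.67). For MHC class II 8 of 8 rose (median 0.86, adjusted p = 4e-04, adjusted p = 0.17 with an estimated correlation).

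In the cytokine and chemokine list 22 of 25 rose and 1 (Ccl11) fell (median 2.67, adjusted p = 3e-15). Ccl3 was at 5.21; in the acute-phase and complement list 12 of 14 rose and 1 (Orm1) fell (median 1.68, adjusted p = 6.6e-08, adjusted p = 0.068 with an estimated correlation). Of the neutrophil markers 16 of 18 rose (median 3.30, adjusted p = 2.6e-10, adjusted p = 0.1 with an estimated correlation). Among monocyte and macrophage markers 20 of 22 rose (median 2.72, adjusted p = 1.4e-18, adjusted p = 0.068 with an estimated correlation), with the glycoprotein gene Gpnmb at 5.19, Trem2 at 4.89 and Fcgr1 at 4.24. In the alternatively activated set 6 of 13 rose and 2 (Retnla and Mgl2) fell, 8 and 2 adjusted over the list alone (median 0.61, adjusted p = 0.0025, adjusted p = 0.17 with an estimated correlation). Of the mast cell markers 6 of 8 rose (median 1.24, adjusted p = 0.0037, adjusted p = 0.28 with an estimated correlation). In the plasma cell list 8 of 13 rose (median 0.79, adjusted p = 0.0022, adjusted p = 0.11 with an estimated correlation), with Igha (2.51) and Mzb1 (2.24). Of the T and NK cell markers 15 of 18 rose, 16 adjusted over the list alone (median 1.37, adjusted p = 5.6e-06, adjusted p = 0.079 with an estimated correlation).

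Fat genes fell in BALB/c at day 18: in the adipocyte identity list 16 of 17 fell (median -1.22, adjusted p = 3.1e-05, adjusted p = 0.24 with an estimated correlation). In the lipid synthesis list 15 of 18 fell, 18 adjusted over the list alone (median -1.11, adjusted p = 2.9e-05, adjusted p = 0.29 with an estimated correlation), with Acacb (-1.89) and Dgat1 (-1.51) after Pck1. Of the matrix and fibrosis genes 10 of 22 rose (median 0.16, adjusted p = 0.037, adjusted p = 0.49 with an estimated correlation). The list's call ended without BALB/c day 18 replicate 4 (0.15, adjusted p = 0.062) or BALB/c control replicate 2 (0.05, adjusted p = 0.24), over a range of 0.0012 to 0.24. For matrix proteases 10 of 12 rose (median 1.07, adjusted p = 2.3e-05, adjusted p = 0.079 with an estimated correlation), with Mmp12 (5.46) and Plau (2.57), and for proliferation 26 of 27 rose (median 1.55, adjusted p = 1.2e-09, adjusted p = 0.19 with an estimated correlation).

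The DBA response at day 18 was measured on 3 treated and 3 control arrays. Its largest increases were in Acod1 (7.23), Cxcl2 (5.83), Cxcl5 (5.80), Clec4e (5.78), Ccl3 (5.65), Trem2 (5.57), Arg1 (5.57) and Chil3 (5.36). The largest decreases were in Cidea, a lipid droplet gene of thermogenic fat (-3.84 ± 0.62), Lep, which encodes leptin (-3.73 ± 0.73), Npr3 (-3.66), Mtarc1 (-3.65), Cox8b (-3.60) and Sncg (-3.57). Here 6166 genes changed, 2911 higher and 3255 lower, with 1310 and 1132 at 2-fold or more and 6957 at an unadjusted p under 0.05.

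Type I interferon-stimulated genes rose in DBA at this time: 29 of 30 rose (median 2.92, adjusted p = 1.3e-23, adjusted p = 0.065 with an estimated correlation). For interferon-gamma response genes and GTPases 13 of 14 rose (median 1.49, adjusted p = 2.9e-07, adjusted p = 0.13 with an estimated correlation). In MHC class I presentation 9 of 11 rose (median 1.07, adjusted p = 0.00017, adjusted p = 0.13 with an estimated correlation), with Tap1 at 2.41. In MHC class II 7 of 8 rose (median 0.83, adjusted p = 0.0014, adjusted p = 0.2 with an estimated correlation).

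At day 18 in DBA, 22 of 25 cytokines and chemokines rose (median 2.82, adjusted p = 4.8e-14, adjusted p = 0.052 with an estimated correlation). In the acute-phase and complement list 12 of 14 rose and 2 (Orm1 and Orm2) fell (median 1.82, adjusted p = 9.7e-06, adjusted p = 0.074 with an estimated correlation), with Lcn2 (3.51) and Cfb (3.09) and Orm1 at -3.14. Among neutrophil markers 17 of 18 rose (median 3.12, adjusted p = 9.8e-09, adjusted p = 0.13 with an estimated correlation), with the granule genes Ngp (4.08 ± 1.00) and Camp (3.98). Among monocyte and macrophage markers 22 of 22 rose (median 3.04, adjusted p = 7.6e-18, adjusted p = 0.065 with an estimated correlation), with Gpnmb (5.10) and Msr1 (4.21). Of the alternatively activated set 9 of 13 rose and 2 (Retnla and Mgl2) fell (median 1.01, adjusted p = 0.00084, adjusted p = 0.13 with an estimated correlation). For mast cells 7 of 8 rose, 7 with 1 lower adjusted over the list alone (median 2.16, adjusted p = 0.00065, adjusted p = 0.2 with an estimated correlation). Of the plasma cell markers 9 of 13 rose (median 1.58, adjusted p = 0.00015, adjusted p = 0.065 with an estimated correlation), with Ighm at 2.21. Of the T and NK cell markers 14 of 18 rose and 1 (Cd8a) fell (median 1.07, adjusted p = 0.00015, adjusted p = 0.13 with an estimated correlation).

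Fat genes fell in DBA at day 18: of the adipocyte identity list 16 of 17 fell, 17 adjusted over the list alone (median -2.06, adjusted p = 4.6e-07, adjusted p = 0.16 with an estimated correlation), with Aqp7 and Acvr1c at -3.06 and -2.73. The 3 treated arrays differed, with mean log2 levels of 9.72 to 11.48 in this list and 8.73 to 11.32 in the mast cell list, and without DBA day 18 replicate 2 the medians were -1.61 and 1.45. Of the lipid synthesis list 17 of 18 fell (median -1.46, adjusted p = 5.3e-06, adjusted p = 0.23 with an estimated correlation). Of the matrix and fibrosis genes 13 of 22 rose and 2 (Col12a1 and Postn) fell, 13 and 4 adjusted over the list alone (median 0.70, adjusted p = 0.017, adjusted p = 0.43 with an estimated correlation), with Timp1 (4.44) and Col1a1 (1.74). Of the matrix proteases 10 of 12 rose (median 1.32, adjusted p = 1.2e-05, adjusted p = 0.065 with an estimated correlation). For proliferation 26 of 27 rose (median 1.65, adjusted p = 3.5e-09, adjusted p = 0.2 with an estimated correlation).

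Change between the days was tested as the difference between the day 18 and day 3 responses of a strain, each within its own code series. In DBA the interferon genes Usp18 (4.14), Irf7 (3.99), Ifit1 (3.90), Ifit3 (3.84), Trim30d (3.73) and Oas3 (3.54) had the larger increase at day 18. Of the type I list, 28 of 30 were higher, 28 adjusted over the list alone, with a median of 2.46 (adjusted p = 2.4e-55). The interferon-gamma (1.19, adjusted p = 7.2e-11; Irgm1 at 1.97), MHC class I (0.78, adjusted p = 2.2e-05; Tap1 at 1.77), T and NK (0.63, adjusted p = 2.7e-05; Il7r at 2.64) and mast cell lists (1.75, adjusted p = 2.1e-06; Tpsab1 at 2.97) were also higher. The adipocyte list was lower (-1.35, adjusted p = 6.1e-09; Acvr1c at -2.03). For these lists adjusted p = 0.094 to 0.15 with an estimated correlation. Sncg (-3.28), Acta1 (-3.10) and Ntrk2 (-2.47) were among the lower genes. Of 545 genes, 321 were higher (58.9%) and 224 lower, with 2389 at an unadjusted p under 0.05; median centring called 539, of which 70.7% were higher. The count was 905, 249, 348, 352, 247, 313 and 356 without DBA day 18 replicate 1 or 3, DBA control replicate 2, DBA day 3 replicate 2 or 3, or DBA control replicate 5 or 6, in that order, and 1239 without BALB/c control replicate 2.

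In BALB/c, Gpnmb (4.06), Syngr1 (2.34), Lonrf3 (2.05) and Clec4n (1.85) were higher at day 18 and Rnase2a (-4.25), Mgl2 (-2.46), Cd209d (-2.07) and Clec10a (-1.84) lower. The alternatively activated macrophage (-0.87, adjusted p = 2.3e-06) and proliferation lists (-1.10, adjusted p = 2.8e-13) were lower, and the monocyte and macrophage (0.50, adjusted p = 1e-05), MHC class II (0.84, adjusted p = 1.7e-05), T and NK (0.56, adjusted p = 0.00019) and mast cell lists (1.01, adjusted p = 0.0038) higher. Among them adjusted p = 0.16 to 0.48 with an estimated correlation. The intestinal epithelial list was higher by 2.20 (adjusted p = 0.0039, adjusted p = 0.68 with an estimated correlation; 0 of 11 called), not called without BALB/c day 18 replicate 2 (1.76, adjusted p = 0.053), over a range of 5.9e-05 to 0.071. The type I interferon list differed by 0.24 (adjusted p = 0.037, adjusted p = 0.89 with an estimated correlation). That call ended without BALB/c day 18 replicate 1, BALB/c control replicate 1, 2, 4 or 7 or BALB/c day 3 replicate 2 (0.04 to 0.29, adjusted p = 0.061 to 0.96), over a range of 2.4e-05 to 0.96. Over all genes 47 differed, 30 higher (63.8%) and 17 lower, with 1511 at an unadjusted p under 0.05; quantile normalization called 55, of which 74.5% were higher. Leaving out 1 array gave 76 and 111 for BALB/c control replicates 1 and 2, 19 and 24 for BALB/c day 3 replicates 1 and 2, and 27 and 31 for BALB/c control replicates 5 and 6. No test set the change between days in BALB/c against that in DBA.

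At day 18 the BALB/c and DBA responses were compared. Ifi44l, an interferon-induced gene (4.58 ± 0.63, adjusted p = 0.00031), Cd22 (1.94) and Prg4 (1.70) were higher in the BALB/c response, and Best1 (-3.04), Rarres1 (-2.84), Spon1 (-2.61), Actn3 (-2.38) and Ccn3 (-2.23) lower. Camera called 6 of 28 lists, and 0 with an estimated correlation. The type I interferon list was lower in BALB/c, at -0.53 (adjusted p = 2.7e-07, adjusted p = 0.84 with an estimated correlation), and 1 of its 30 genes, Stat2, was lower, 2 adjusted over the list alone. The adipocyte list was higher (0.88, adjusted p = 0.0024, adjusted p = 0.84 with an estimated correlation), a call that ended without DBA day 18 replicate 2 (0.39, adjusted p = 0.25), over a range of 1.7e-06 to 0.25. The intestinal epithelial list was higher by 2.35 (adjusted p = 0.0044, adjusted p = 0.84 with an estimated correlation; 0 of 11 called, 2 adjusted over the list alone). The mast cell (-0.84) and MHC class I lists (-0.25) were lower, each at adjusted p = 0.043 and adjusted p = 0.84 with an estimated correlation, with 0 of 8 and 0 of 11 called. The mast cell call ended without BALB/c day 18 replicate 2 or 3, BALB/c control replicate 1 or 4, DBA day 18 replicate 2 or 3 or DBA control replicate 2 (-0.85 to -0.10, the latter without DBA day 18 replicate 2; adjusted p = 0.052 to 0.72), over a range of 1.7e-07 to 0.72. The MHC class I call ended without BALB/c day 18 replicate 2 or 3, BALB/c control replicate 1, 3 or 4, DBA day 18 replicate 1 or 3 or DBA control replicate 2 or 3 (-0.28 to -0.19, adjusted p = 0.066 to 0.21), over a range of 8.6e-05 to 0.21. In total 128 genes differed, 58 higher and 70 lower, with 2104 at an unadjusted p under 0.05. This was 48, 51, 361, 48, 35, 57, 42 and 64 without BALB/c day 18 replicate 2 or 3, DBA day 18 replicate 1, 2 or 3, or DBA control replicate 1, 2 or 3, in that order, and 270 without BALB/c control replicate 2.

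The Ifi200 family, interferon-inducible genes that include Mndal, was followed in every group because the series is about Mndal. Its 6 tested members were Mndal, Ifi202b, Ifi203, Ifi204, Ifi207 and Ifi209. Ifi213 and Aim2 stayed below the dim filter, as did Cdkn2a. The Mndal signal in the day 3 code series was 3930 ± 415 in BALB/c controls, 2010 ± 625 in F1 controls and 46.1 ± 12 in DBA controls (SD, n = 3), and 8520 ± 1830, 8090 ± 456 and 51.3 ± 50.3 in the treated arrays. At day 18 it was 7030 ± 930 in treated BALB/c against 2400 ± 1230 in their controls (SD, n = 4), and 140 ± 17 in treated DBA against 45.1 ± 19 (SD, n = 3). At day 3 Ifi202b rose by 2.20 ± 0.25 in BALB/c, 2.99 ± 0.25 in F1 and 2.10 ± 0.25 in DBA (log2, SE). Ifi207 rose by 1.41 ± 0.23 in BALB/c and 2.49 ± 0.23 in F1, and Ifi204 by 1.81 ± 0.28 in BALB/c. With signals under the dim filter set to it, Ifi209 rose by 2.43 in BALB/c and 4.16 in F1, and Ifi204 by 2.82 in F1. In DBA Ifi209, Ifi204 and Ifi207 were not called (adjusted p = 0.15, 0.081 and 0.36). At day 18 Ifi202b rose by 2.48 in BALB/c and 3.27 in DBA, and Ifi207 by 2.08 in BALB/c. With signals at the filter, Ifi209 and Ifi204 rose by 3.43 and 1.73 in BALB/c, and Ifi209, Ifi204 and Ifi207 by 3.82, 2.64 and 3.00 in DBA.

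Mndal rose by 2.04 ± 0.43 in F1 at day 3 and by 1.79 ± 0.37 in BALB/c at day 18. In DBA at day 18 it was called higher (adjusted p = 0.017) from controls under the dim filter of 103.7, so no size is given. That call ended without DBA day 18 replicate 2 (adjusted p = 0.055) or DBA control replicate 3 (adjusted p = 0.084), over a range of 0.00018 to 0.27, and a second Mndal probe set was not called (adjusted p = 0.78). In DBA at day 3 both groups averaged under the filter, so neither a change nor a difference from another response is given. In BALB/c at day 3 Mndal was called at 1.10 ± 0.43 (adjusted p = 0.049), but not without BALB/c day 3 replicate 1, 2 or 3 or BALB/c control replicate 5, 6 or 7 (0.93 to 1.21, adjusted p = 0.063 to 0.16), over a range of 0.00036 to 0.16. The second probe set gave 1.39 ± 0.41 (adjusted p = 0.011). Ifi203 averaged under the filter in every group. So did the controls of Ifi209 in every strain and series, of Ifi204 in all but BALB/c in the day 3 series, and of Ifi207 in DBA at day 18, so the sizes of these changes depend on the offset. The family's members are close paralogs, so part of a probe set's signal may come from another member.

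As a list, 5 of 6 in the family (all but Ifi203) rose in BALB/c at day 3, 6 adjusted over the list alone (median 1.61, adjusted p = 0.00017, adjusted p = 0.088 with an estimated correlation). In F1 at day 3, 5 of 6 (all but Ifi203) rose (median 2.65, adjusted p = 2.4e-06). In DBA at day 3, 1 of 6 (Ifi202b) rose (median 0.48, adjusted p = 0.15). At day 18, 5 of 6 (all but Ifi203) rose in BALB/c (median 1.94, adjusted p = 8.9e-05, adjusted p = 0.079 with an estimated correlation). In DBA at day 18, 6 of 6 were called (median 3.16, adjusted p = 1.4e-05, adjusted p = 0.065 with an estimated correlation). With signals under the filter set to it, the medians were 1.76 in BALB/c, 2.73 in F1 and 0.24 in DBA at day 3, and 2.00 in BALB/c and 2.82 in DBA at day 18. In these 5 responses 2, 3, 4, 3 and 5 members had controls under the filter, so the differences between family responses depend on the offset too. The F1 response exceeded the DBA one by 2.14 (3 of 6, 5 adjusted over the list alone; adjusted p = 3.8e-10), in Ifi209, Ifi207 and Ifi204. It exceeded the BALB/c one by 0.97 (0 of 6, 3 adjusted over the list alone; adjusted p = 0.00027, adjusted p = 0.095 with an estimated correlation). BALB/c exceeded DBA at day 3 by 1.13 (1 of 6, 3 adjusted over the list alone; adjusted p = 3.4e-05, adjusted p = 0.14 with an estimated correlation). BALB/c lay below DBA at day 18 at -0.84 (1 of 6, 3 adjusted over the list alone; adjusted p = 0.0084, adjusted p = 0.84 with an estimated correlation). In DBA the day 18 response exceeded that at day 3 by 2.03 (3 of 6, 6 adjusted over the list alone; adjusted p = 4.2e-10).

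Of the differences between BALB/c and DBA, the 1 called at day 3, Ifi209 (adjusted p = 0.023), lost its call without BALB/c day 3 replicate 1 or 3, BALB/c control replicate 6 or 7, DBA day 3 replicate 3 or DBA control replicate 5 (adjusted p = 0.052 to 0.084), over a range of 0.0011 to 0.084. The 1 called at day 18, Ifi204 (lower in BALB/c, adjusted p = 0.04), lost its call without BALB/c day 18 replicate 2, 3 or 4, BALB/c control replicate 3, DBA day 18 replicate 3 or DBA control replicate 1, 2 or 3 (adjusted p = 0.059 to 0.15), over a range of 0.00095 to 0.24. Controls of both lay under the filter in both strains, so no size is given. For Mndal itself the F1 response differed from the BALB/c one by 0.94 ± 0.61 (adjusted p = 0.77). Mtor, a plasmacytoma candidate, fell in DBA at day 3 (-0.54) and in BALB/c and DBA at day 18 (-0.59 and -0.76), and stood at -0.22 ± 0.12 (adjusted p = 0.17) in BALB/c at day 3. In F1 at day 3 Mtor was called at -0.33 ± 0.12 (adjusted p = 0.032), but not without F1 day 3 replicate 1 or 3 or control replicate 1 or 2 (-0.34 to -0.29, adjusted p = 0.065 to 0.12), over a range of 2e-04 to 0.45. Its second probe set was called in no response (-0.37 to 0.11, adjusted p = 0.13 to 0.72).

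**Figure D3:**
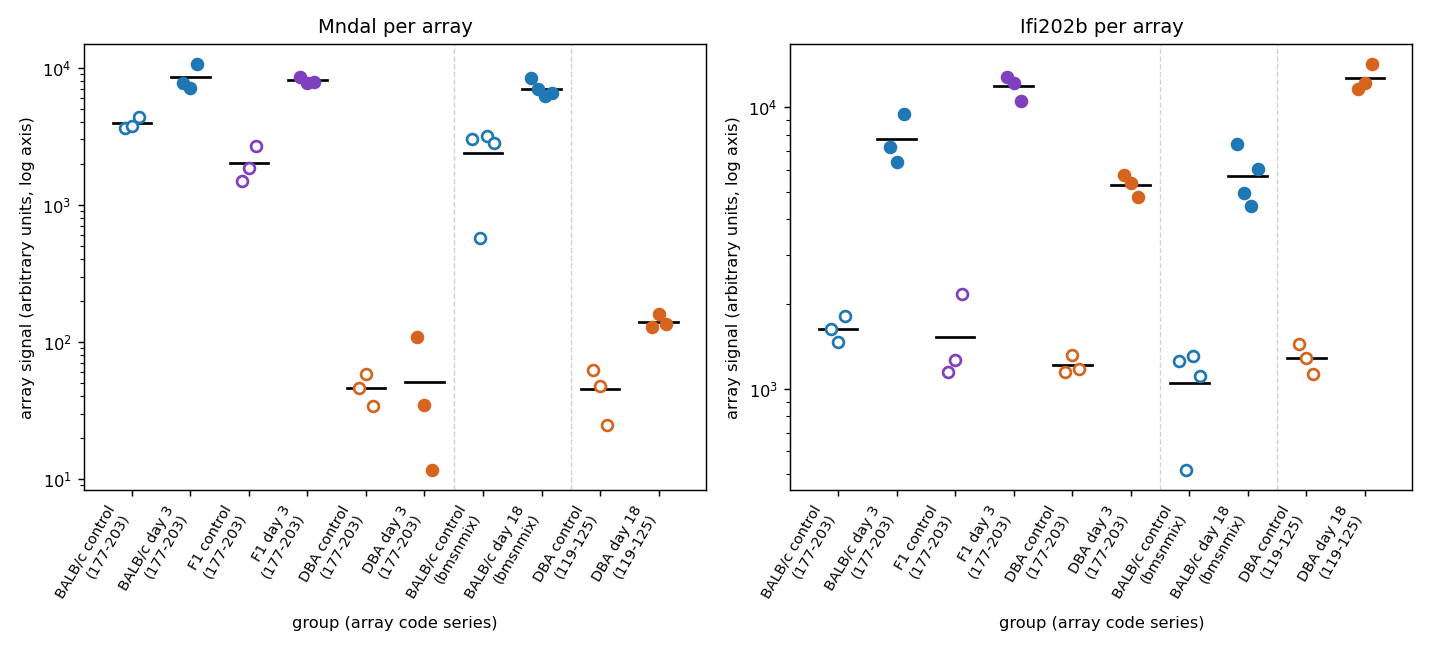
Array signal (vertical log axis, arbitrary units) of Mndal and Ifi202b on each array by strain and day; open symbols are controls, filled symbols treated arrays and black bars group means, and dashed lines part the code series. Mndal averages 46.1 in DBA controls of the day 3 code series against 3930 in BALB/c and 2010 in F1 controls, whereas Ifi202b averages 1220, 1630 and 1530.

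Untreated DBA and BALB/c mesentery were compared in the day 3 code series, with 3 arrays each. DBA was higher in Mrap2 (4.85), Stab2 (3.78), Cldn34c1 (3.19), Mcpt2 (2.77), Elovl3 (2.75) and Otop1 (2.70), where Mcpt2 is a mast cell protease gene. DBA was lower in Mndal (46.1 against 3930, at least 37.8-fold with each DBA array set to the dim filter of 103.7; adjusted p = 7.1e-10), Rarres1 (-5.42), Tmem45b (-5.25), Aqp11 (-4.74), Tgm3 (-4.39) and Gbp2b (-3.78). Mtor was higher in DBA by 0.50 ± 0.12 (second probe set 0.49, not called). B cell markers were lower in DBA (6 of 12, with 1 higher; median -0.65, adjusted p = 0.00042, adjusted p = 0.67 with an estimated correlation), including Ms4a1 (-1.49), Cxcr5 (-1.26) and Cd79a (-1.26), and Ighm was lower, at -1.59. Of the mesothelial markers 3 of 13 (Wt1, Krt19 and Gpm6a) were lower, 4 adjusted over the list alone (median -0.53, adjusted p = 0.00086, adjusted p = 0.67 with an estimated correlation). The proliferation list was higher in DBA, with 2 of 27 (Cdk1 and Bub1b) called (median 0.44, adjusted p = 0.0089, adjusted p = 0.96 with an estimated correlation), but not without DBA control replicate 4 (0.25, adjusted p = 0.29), over a range of 2.4e-05 to 0.29. Of the type I interferon-stimulated genes 3 of 30 (Ifi27l2a, Xaf1 and Rtp4) were lower (median -0.33, adjusted p = 0.0056, adjusted p = 0.96 with an estimated correlation). The Ifi200 family (-0.33, adjusted p = 0.035, adjusted p = 0.75 with an estimated correlation) was lower, a call that ended without BALB/c control replicate 5 (-0.26, adjusted p = 0.057) or DBA control replicate 4 (-0.24, adjusted p = 0.12), over a range of 0.013 to 0.12. Over single probe sets limma called Mndal lower. The other members were not called (adjusted p = 0.32 to 0.98), so a lower level beyond Mndal was not shown. In all 997 genes differed, 523 higher and 474 lower in DBA, 160 and 159 by at least 2-fold, with 2460 at an unadjusted p under 0.05. The count was 631 without BALB/c control replicate 7, 659 without DBA control replicate 5 and 1660 without BALB/c control replicate 2. Probes were designed on a reference sequence, so a strain's sequence variants can lower its signal without a change in the transcript.

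F1 controls were set against the mean of both parents' controls. Tmem45b (3.37), Sult1e1 (3.22), Rarres1 (1.80) and Mrap2 (1.68) were above the log2 mean, and Tuba8 (-1.61) and Cldn34c1 (-1.49) below it. Mndal was also called above it (adjusted p = 0.016), with no size as DBA controls lie under the filter. Without F1 control replicate 2 (adjusted p = 0.082) or 3 (adjusted p = 0.16) it was not called, over a range of 1.8e-06 to 0.56. On the linear scale the F1 controls' 2010 lay near the middle of 46.1 and 3930. Log2 means lie under linear ones, so Rarres1 and Mrap2 may lie midway too. Camera called 6 of 28 lists here, and 0 with an estimated correlation. In all 40 genes differed (5 with the Xist term, chosen after seeing the data, and 1309 with array weights), 21 higher (52.5%) and 19 lower, with 1237 at an unadjusted p under 0.05; median centring called 52, of which 32.7% were higher. Without F1 control replicates 1, 2 and 3 the count was 25, 22 and 21, and without BALB/c control replicate 2 it was 154. All F1 controls were low in Xist and all parental ones of this series high.

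Controls of one strain also differed between code series. In DBA, Npas2 and Arntl, which drive the circadian clock, were higher in the DBA day 18 code series than in the day 3 series (signals of 403 against 4.43 and 799 against 58.2). Their targets Dbp (-4.92 ± 0.62), Per3 (-3.87 ± 0.38) and Per2 (39.8 against 922) were lower. In BALB/c the pancreatic gene Cpa1 was higher in the day 18 series (87 to 1598, with 110900 on control replicate 2, against 3 to 7.8). Per2 was lower there (-3.36 ± 0.33). The pancreatic list was called in BALB/c (median 5.50, 11 of 13 higher; adjusted p = 5e-05, adjusted p = 0.99 with an estimated correlation) and not in DBA (0.52, adjusted p = 0.74). Between the series 3430 genes differed in BALB/c, 1693 higher (49.4%) and 1737 lower, and 3839 in DBA, 1808 higher (47.1%) and 2031 lower. Median centring called 3549 and 3972, of which 30.5% and 27.9% were higher. It moved the median of all genes in DBA from 0.03 to -0.10. High and low Xist controls numbered 2 and 2 in the BALB/c day 18 series and 1 and 2 in that of DBA, against 3 and 0 each in the day 3 series.

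**Figure D4:**
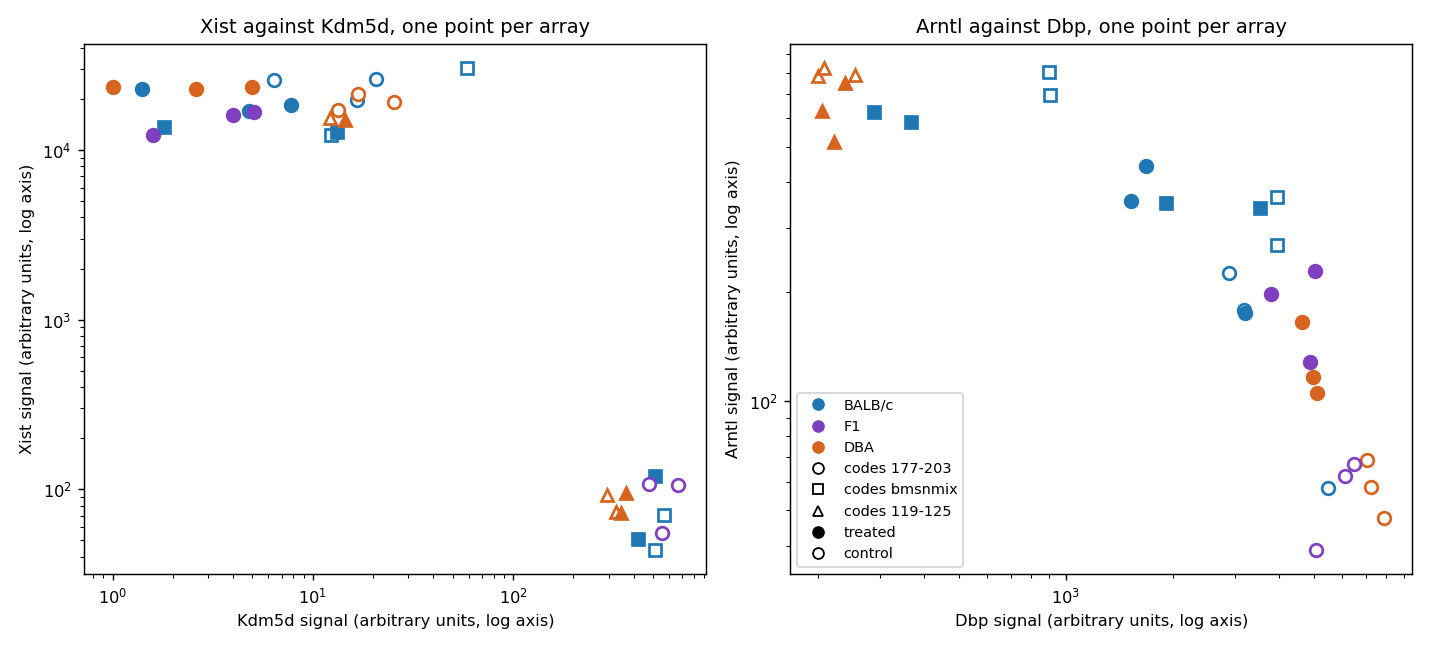
Signal of Xist against Kdm5d and of Arntl against Dbp, with one point per array on log axes (arbitrary units, signals under 1 drawn at 1); open symbols are controls, filled symbols treated arrays, colour the strain and marker shape the code series. High Xist arrays lie at 12273.7 or more and low ones at 120.1 or less, and the DBA arrays of the day 18 code series have Dbp means of 221 and 222 against 4900 and 7400 in the day 3 series.

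Responses in different strains and days had many genes in common. In BALB/c and F1 at day 3, 1784 genes were higher in both (442 expected of independent lists) and 1623 lower in both (402); BALB/c and DBA had 1575 (390) and 1267 (300), and F1 and DBA 1506 (395) and 1208 (313).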

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

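The tests chosen only after the result was seen were those of probe alleles, parental controls for the sex-linked difference, monocyte numbers, pancreatic tissue, RNA ends, time of day, and the splits of differences between responses.

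The type I interferon list responded weakly in DBA at day 3: the BALB/c response exceeded it by a median of 1.56, and the F1 response by 2.67. Probes that miss DBA alleles are argued against by the DBA day 18 response, which exceeded that at day 3 by 2.46. The slope of DBA on BALB/c changes was 0.76 ± 0.005 over the 4697 genes outside the interferon lists called in F1 at day 3. It was 0.26 ± 0.034 over the 30 list genes (SE over genes) and 0.699 over all genes. This argues against a weaker response of all genes as the whole cause, but not as part. Fewer recruited monocytes and macrophages are argued against by their list's difference of -0.01. A strain difference in interferon timing stays open as an untested hypothesis, and the days lie in different code series.

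BALB/c and DBA controls differed alike between code series, with Pearson's r of 0.554 across genes and 1900 genes called in both (1012 expected of independent lists), 1864 of them in the same direction in both strains. Pancreatic tissue is argued against as a shared cause by the pancreatic list in DBA, at 0.52. The Gapdh 3' to 5' ratio was higher by 0.268 in the day 3 series, and RNA ends cannot be told apart from the code series, which they follow. Tissue taken at another time of day has the values it needs: in DBA all 13 clock genes were called in the direction of their phase, including the 8 not noticed first, and it may account for part of the DBA difference, as a hypothesis, while a batch effect stays open. In BALB/c 9 of 13 were, and 2 were called in the opposite direction, which leaves time of day open there. These were Nr1d1 (1.21, adjusted p = 0.017), not called without BALB/c control replicate 4, 5 or 7 (1.04 to 1.08, adjusted p = 0.051 to 0.076, over a range of 0.00046 to 0.13), and Nfil3 (-0.84, adjusted p = 0.012), not called without BALB/c control replicate 5 (-0.62, adjusted p = 0.1, over a range of 0.0021 to 0.17). Each series held 1 day of treatment, so this bears on day 18 against day 3.

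The F1 response exceeded that of BALB/c in the type I interferon list by 0.99. A sex-linked difference between treated and control F1 arrays is argued against by the difference of 1.19 with parental controls, which share the treated arrays' Xist pattern. F1 arrays from another strain are argued against by the controls' median position of 0.58 between BALB/c (0) and DBA (1), over 319 genes. An effect of the hybrid genome stays open as an untested hypothesis. The list's adjusted p with an estimated correlation was 0.055.

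Differences between responses were tested directly, and stand for a closer look because 65 genes differed for BALB/c against DBA at day 3, 128 at day 18, 29 for F1 against BALB/c, 263 for F1 against DBA, 47 for day 18 against day 3 in BALB/c and 545 in DBA. F1 against DBA also differed by medians of 2.14 in the Ifi200 family, 1.87 in the interferon-gamma list, 1.27 in MHC class I and 0.97 in T and NK cells. In DBA, day 18 exceeded day 3 by 2.03 in the Ifi200 family.

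Single arrays stood far from the rest of their group in 9 of 93 tests, where chance gives about 1 in 20 groups. BALB/c control replicate 2 stood apart in the mean log2 level of pancreatic (16.7), matrix (11.4), plasma cell (10.8), alternatively activated macrophage (8.43) and plasmacytoma candidate genes (9.57), and in the log2 of its highest signal (17). BALB/c control replicate 7 stood apart in mesothelial markers (11.1), BALB/c day 18 replicate 2 in alternatively activated macrophage markers (10.1) and DBA control replicate 2 in hypoxia and stress genes (10.1).

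Splits of the same arrays excluded chance for the BALB/c day 18 response (5715 genes; highest other split 3010), BALB/c against DBA at day 3 (65; 1) and day 18 (128; 288, in 4 of 100 splits as large), F1 against BALB/c (29; 223, in 2 of 100) and DBA (263; 5), day 18 against day 3 in BALB/c (47; 11) and DBA (545; 67), and the BALB/c code series (3430; 2435). The 3010 came from BALB/c control replicate 2 grouped with 3 treated arrays. For differences between responses the splits argued against chance only after strain and series differences were removed, a step added after the result without it was seen. With them left in, 7 to 17 of 100 splits were as large. Chance was not excluded for F1 against mid-parent controls, with 9 of 84 splits as large (40 genes; 843 with the BALB/c controls as the group), which points to a structure of the samples, the strains. The splits with 223 and 288 mixed the strains and called more genes than the real ones, which points to a structure of the samples that was not tested. The 10 splits were too few for a share under 0.05 in the BALB/c (4618; 0), F1 (4752; 89) and DBA (3877; 1) day 3 responses, the DBA day 18 response (6166; 0), DBA against BALB/c controls (997; 1) and the DBA code series (3839; 2).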

How the results depend on the processing

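Tests chosen only after the result was seen were the Xist term over all arrays or within the BALB/c day 18 code series, parental controls in place of F1 controls, and leaving BALB/c control replicate 2 out of comparisons that do not rest on it. No paired analysis was possible because replicate numbers follow accession order and pair no arrays. In the BALB/c day 18 code series replicates 1 and 2 were high in Xist and 3 and 4 low in both groups, and a term for this within the series gave 5818 genes for the response, 151 against DBA and 64 against day 3. Of 361 alternative counts of called genes, 283 stayed within 1.5 times the count reported. Direction and side of the threshold were kept in 4291 of 4587 list values and 8995 of 9133 values of named genes over the alternatives. Both offset choices, both dim filters, median centring, no variance trend and the mean over probe sets moved none of the 15 counts by more. With an estimated correlation 115 of 199 list results lost their call; fry ended 34 and added 16. Dim genes near the offset limit what signal over background can show, and where counts moved, the cause was not tested except where fewer arrays entered.

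Array weights gave 5872 genes for DBA at day 3, 930 and 1281 for BALB/c against DBA at day 3 and 18, 712 for F1 against BALB/c, 1637 for F1 against DBA, 548 and 3036 for day 18 against day 3 in BALB/c and DBA, 2131 for DBA against BALB/c controls and 1309 for F1 against mid-parent controls; BALB/c control replicate 2 had a weight of 0.0558. Separate fits, with fewer arrays for the spread, gave 3423 for BALB/c at day 18, 389 and 5 for BALB/c against DBA at day 3 and 18, 181 for F1 against BALB/c, 398 for F1 against DBA, 23 and 821 for day 18 against day 3, 136 for F1 against mid-parent and 409 for the BALB/c code series. Without the code series term, F1 against BALB/c gave 63, day 18 against day 3 gave 1084 and 4147, and F1 against mid-parent 89. Quantile normalization gave 273 for BALB/c against DBA at day 18 and 823 for day 18 against day 3 in DBA, the ordinary linear model 31 for day 18 against day 3 in BALB/c, and probe sets singly 71 for F1 against mid-parent. The Xist term gave 5 for F1 against BALB/c and 5 for F1 against mid-parent, and parental controls 180 against BALB/c and 587 against DBA.

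The type I interferon list kept its median with an estimated correlation but not its call in BALB/c (2.12, adjusted p = 0.088) and DBA (0.38, adjusted p = 0.6) at day 3, in BALB/c (2.47, adjusted p = 0.079) and DBA (2.92, adjusted p = 0.065) at day 18, and in F1 against BALB/c (0.99, adjusted p = 0.055). Xist in F1 at day 3 turned to -0.25 with the Xist term and -0.52 with parental controls, and Eif2s3y to 0.05 with parental controls. The intestinal list in F1 against BALB/c turned to 0.07 with array weights and ran from -1.83 to 0.4 with 1 array left out.

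Leaving out 1 array in turn gave 3823 to 5748 genes for BALB/c, 3760 to 5887 for F1 and 2593 to 5064 for DBA at day 3, 4853 to 6276 and 5164 to 7188 for BALB/c and DBA at day 18, 23 to 200 and 35 to 361 for BALB/c against DBA at day 3 and 18, 6 to 166 for F1 against BALB/c, 187 to 534 for F1 against DBA, 19 to 111 and 247 to 1239 for day 18 against day 3, 631 to 1660 for DBA against BALB/c controls, 21 to 154 for F1 against mid-parent, and 2429 to 3825 and 2904 to 5067 for the code series. The highest came without BALB/c control replicate 2 except for BALB/c against DBA at day 18, without DBA day 18 replicate 1. The interferon list's median ran from 1.91 to 2.3, 3.31 to 3.47 and 0.32 to 0.53 in BALB/c, F1 and DBA at day 3, from 2.24 to 2.67 and 2.72 to 3.15 at day 18, and in the differences from 1.31 to 1.71, 0.78 to 1.2, 2.54 to 2.84 and 2.24 to 2.56.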

Other observations

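The clock genes were tested only after the result was seen, as a list chosen for the code series difference.

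In the BALB/c day 18 code series, the Dbp signal was 895, 902.4, 3946.7 and 3944.2 on control replicates 1 to 4 and 288.4, 366, 3532.7 and 1919.2 on treated replicates 1 to 4, and Arntl was 802.5, 696.4, 365.5 and 268.6 on the controls and 622.9, 587.7, 340.4 and 350 on the treated arrays. High Dbp arrays had the lower Arntl in both groups, and they were also the arrays low in Xist.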
